A study of Homo sapiens with 30 samples.

How the data were processed

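Guide abundance was measured by amplicon sequencing of guide cassettes from genomic DNA in 29 libraries of 5 human cell lines that carry a doxycycline-inducible RfxCas13d and a pooled lentiviral guide library. Cells were harvested on days 0, 7 and 14 after doxycycline was added. Each line and day had 2 libraries from separate infections, per the labels' protocols, except K562 day 0, which had 1. Those protocols state that a K562 day 0 replicate was left out because little DNA was recovered, so the second K562 day 0 library was not analysed here. THP1 cells were kept under puromycin far longer than the other lines before induction and in another serum, per the same protocols, so line and selection history cannot be told apart for THP1.

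The values are raw whole-number read counts per guide, as the authors deposited them, in 1 table of 75262 guides. The submitters' processing notes name cutadapt 1.13, Bowtie 1.1.2, DESeq2, MultiQC and the GRCh38 build without giving their roles. The filters and mismatches allowed when reads were assigned to guides are not given in the sources used here. Guides are identified by a class prefix and a number, and the table does not pair them with sequences, targets or genes. The prefixes were read, from knowledge of such libraries and not from the table, as guides against essential protein-coding genes (gEss, 1000 guides), guides against long non-coding RNAs (gL, 73262 guides) and non-targeting guides (gNT, 1000 guides).

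The design fixed before the data were examined tested each lncRNA target by combining its guides, and listed lncRNA genes to be described by name. Neither could be run without a map from guides to targets, so the tests were made per guide and per guide class, no gene is named, and the gene lists have no result. The rule for named items reduced to at most 2 depleted and 2 enriched gL guides per line: those with the smallest p at day 14 against day 0 whose change had the same sign in both replicates.

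Guides with a mean count of at least 30 over all libraries were tested, which left 75163 guides: 1000 gEss, 73165 gL and 998 gNT. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit with its newer estimation, then glmQLFTest, two-sided) in 1 model of 15 groups, which left 14 residual degrees of freedom. The estimated negative binomial dispersion was 0.0653. P-values were adjusted by the Benjamini-Hochberg method over all tested guides of a comparison, and a guide was called at an adjusted p under 0.05. Depleted means a call with a negative log2 fold change and enriched a call with a positive one. The comparisons were day 14 against day 0, day 7 against day 0 and day 14 against day 7 in each line, and the day 14 change of each line against the mean change of the other 4. With K562 day 0 at 1 library, its comparisons with day 0 assume that this library varies like the other groups.

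The gNT guides show how the shared estimate of spread fits each line. At day 14 against day 0, an unadjusted p under 0.05 was reached by 11.3% of gNT guides in HAP1, 4.01% in HEK293FT, 6.91% in K562, 5.21% in MDA-MB-231 and 0.301% in THP1. The test was therefore too permissive in HAP1 and too strict in THP1, and counts of calls should be compared between lines with that in mind.

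Calls of gL and gNT guides were compared with a two-sided Fisher's exact test, in a family of 40 tests. Class medians were compared with two-sided permutation tests over guides with 100000 resamples, in a family of 20 tests. Both treat guides as independent, which gL and gEss guides with neighbouring numbers were not, so their p-values are too small. Shares of guides carry 95% exact Clopper-Pearson intervals, which cover the number of guides and not the spread between libraries. Class medians per library were taken from log2 counts scaled to library size (CPM) relative to the mean of the line's day 0 libraries, minus the gNT median of the same library.

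The per-guide test was tested on simulated counts drawn with the real means and library sizes, a dispersion of 0.04 and 200 changed guides among 75163. Of guides lowered by 2 on the log2 scale it recovered 98% in the simulated HAP1 comparison, 96% in HEK293FT, 70% in K562, 98% in MDA-MB-231 and 100% in THP1. Of guides lowered by 1 it recovered 10%, 6%, 10%, 10% and 16% in the same order. False calls among the unchanged guides numbered 2, 4, 2, 10 and 5 in that order. The fitted dispersion was 0.0653 and the number of changed guides in the data is unknown, so these values do not carry over directly.

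Totals per library ran from 6209674 to 48487291 reads, with medians of 81 to 640 reads per guide. Reads were not counted by molecule, so amplification adds spread beyond counting error. Within every group of 2 libraries the counts differed by more than sampling noise (chi-square per degree of freedom 2.73 to 25.7), so no library was a copy of another. That they came from separate infections rests on the labels, since repeated amplification of the same DNA would also differ by more than sampling noise.

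The alternatives tried were DESeq2 size factors, TMM factors from gNT guides alone, no filter on low counts, a mean count of at least 100, DESeq2 1.42.0 in place of edgeR, each line fitted alone, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were thinning of all libraries to 6209674 reads, removal of 380 guides that stood more than 10 times above every other library of their line in 1 library, and removal of 1 replicate's later libraries in HEK293FT or in K562. Class medians, resampling and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.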

Results

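Guide abundance was followed for 14 days in 5 human cell lines carrying an inducible RfxCas13d. RfxCas13d is an RNA-guided ribonuclease that cuts RNA and leaves the genome intact, so a guide lowers its target transcript. In a pooled screen each cell carries a guide, and a guide whose target the cells need becomes rarer as they divide. The lines were HAP1, a near-haploid line from chronic myeloid leukaemia, HEK293FT, a transformed embryonic kidney line, K562, a chronic myeloid leukaemia line, MDA-MB-231, a breast adenocarcinoma line, and THP1, an acute monocytic leukaemia line. Libraries were made before induction (day 0) and on days 7 and 14, with 2 separate infections per line and day except K562 day 0, with 1. Guides fell into 3 classes: 1000 gEss guides, read here as directed at essential protein-coding genes, 73262 gL guides, read as directed at long non-coding RNAs, and 1000 gNT guides, read as non-targeting controls.

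THP1 libraries were the deepest, with totals of 23692480 to 48487291 reads. Totals were 6209674 to 9982557 reads in HAP1, 8666509 to 12082095 in HEK293FT, 8989865 to 17368617 in K562 and 10715025 to 19160021 in MDA-MB-231. Replicate libraries of day 14 correlated over guides with a Pearson r of 0.93 in THP1, 0.88 in MDA-MB-231, 0.76 in HAP1, 0.70 in HEK293FT and 0.66 in K562. Those of day 0, the baseline of most comparisons, correlated by 0.879 in THP1, 0.666 in MDA-MB-231, 0.747 in HAP1 and 0.526 in HEK293FT. In HEK293FT, 380 guides had, in 1 library, more than 10 times the abundance of every other library of the line. These spikes took 12.5% of the reads of day 0 replicate 1 and 1.11% to 5.33% of the reads of the other HEK293FT libraries. No guide met this definition in HAP1, K562, MDA-MB-231 or THP1, where the lone K562 day 0 library was not searched.

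The gEss guides test whether the effector depleted guides against genes that cells need. They lost abundance relative to gNT guides in all 5 lines. At day 14 the median gEss guide stood, on the log2 scale and relative to gNT guides, at -1.60 ± 0.20 in HAP1 and -1.10 ± 0.18 in MDA-MB-231 (SD, n = 2 libraries). The same value was -0.75 ± 0.02 in THP1, -0.40 ± 0.06 in K562 and -0.31 ± 0.06 in HEK293FT (SD, n = 2). The median gEss guide thus kept 32.9% of its day 0 abundance in HAP1, 46.5% in MDA-MB-231, 59.3% in THP1, 75.9% in K562 and 80.8% in HEK293FT. The SDs above leave out the spread of the day 0 baseline. At day 0 the gEss SD was 0.141 in HAP1, 0.116 in HEK293FT, 0.014 in MDA-MB-231 and 0.004 in THP1, while K562 had 1 library. Without day 0 replicate 1 the HEK293FT value in edgeR was -0.208, against -0.291 with it. A gEss guide lay below a gNT guide with a probability of 0.841 in HAP1, 0.879 in MDA-MB-231, 0.84 in THP1, 0.715 in K562 and 0.736 in HEK293FT. Each of these had a permutation p of 1e-05, the smallest that 100000 resamples can give, and an adjusted p of 1.67e-05.

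As a class, gEss guides already lay below gNT guides at day 7. Their median relative to gNT guides was then -0.86 ± 0.24 in HAP1, -0.50 ± 0.02 in MDA-MB-231, -0.37 ± 0.14 in HEK293FT, -0.29 ± 0.12 in K562 and -0.26 ± 0.004 in THP1 (SD, n = 2), each with a permutation p of 1e-05. At day 7 against day 0 edgeR called 428 of 1000 gEss guides depleted in HAP1, 210 in MDA-MB-231, 115 in THP1 and 93 in HEK293FT. In K562 it called 0, with 219 changed in either direction at an unadjusted p under 0.05. The K562 shift at day 7 is thus one of the class, and it rests on 1 day 0 library. From day 7 to day 14, libraries with the same replicate number were compared guide by guide, relative to gNT guides. The median gEss change was negative in both replicates of HAP1, K562, MDA-MB-231 and THP1. In K562 this depends on taking the numbers as pairs, since the class median of day 14 replicate 1 (-0.358) lay above that of day 7 replicate 2 (-0.379). In HEK293FT replicate 1 the median change was -0.18 on the log2 scale (95% bootstrap interval over guides -0.21 to -0.15), and the class median went from -0.273 to -0.351. In the HEK293FT libraries labelled replicate 2 the median change was 0.25 (0.23 to 0.29), and the class median went from -0.473 to -0.265. Any direction between these days in HEK293FT thus rests on the replicate chosen.

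**Figure D1:**
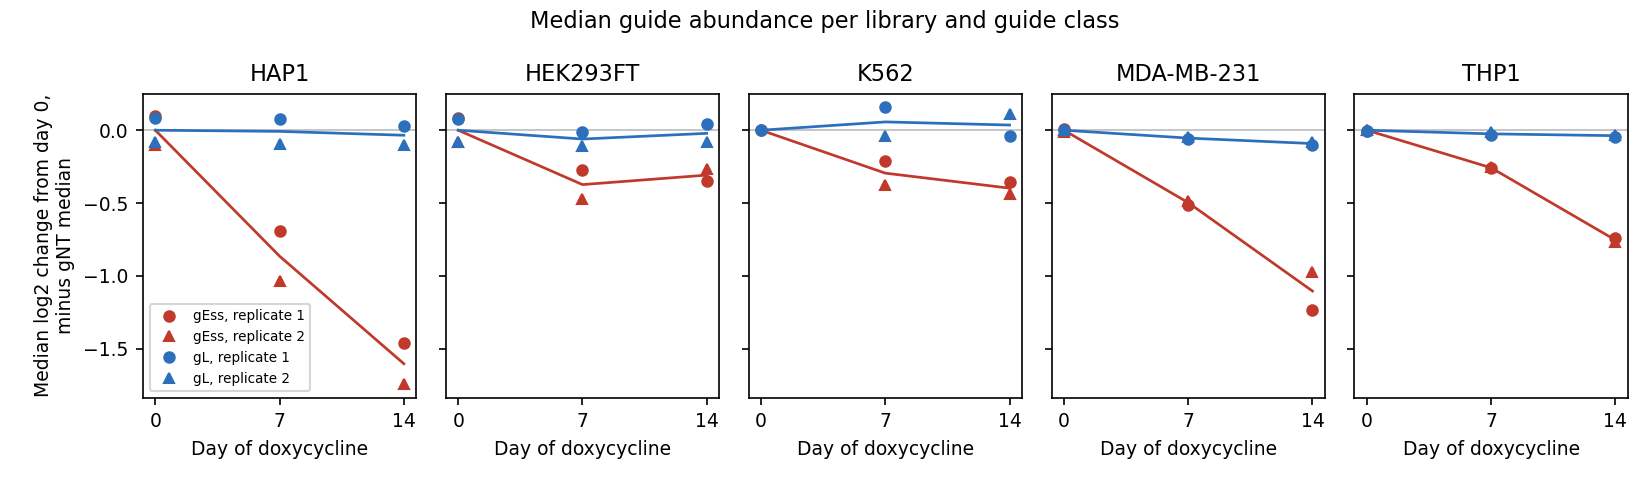
Median log2 abundance of gEss (red) and gL (blue) guides per library, relative to the line's mean at day 0 and minus the gNT median of the library, against days of doxycycline. Circles and triangles are the libraries of replicates 1 and 2 and lines join their means. The gEss mean at day 14 is -1.60 in HAP1 and -0.31 in HEK293FT, while the gL means stay between -0.09 and 0.06.

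As a class, gL guides changed little. At day 14 their median relative to gNT guides was -0.09 ± 0.02 in MDA-MB-231 and -0.04 ± 0.01 in THP1 (SD, n = 2), and both medians differed from gNT guides (adjusted p 1.67e-05 and 4.29e-05, permutation test). In K562 the gL median lay above that of gNT guides (adjusted p = 0.00554, permutation test), but by 0.04 ± 0.11 (SD, n = 2), less than the spread between its libraries. HAP1 and HEK293FT did not pass at day 14 (adjusted p = 0.0813 and 0.0721, permutation tests). At day 7 the gL median was lower in HEK293FT, MDA-MB-231 and THP1, higher in K562 and not different by this test in HAP1 (adjusted p 3.08e-05, 1.67e-05, 0.000293, 0.0106 and 0.471, permutation tests), and in HEK293FT and K562 these differences were also below the spread between libraries.

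At day 14 against day 0, edgeR's quasi-likelihood test called 598 of 1000 gEss guides depleted in HAP1, 504 in MDA-MB-231, 429 in THP1, 130 in K562 and 78 in HEK293FT. The named gEss guides gEss_000154 in HAP1 and gEss_000063 in THP1 had log2 fold changes of -4.30 (SE 0.30) and -3.88 (SE 0.30), with adjusted p-values of 6.42e-11 and 3.93e-10 in edgeR. Among 998 gNT guides the depleted calls were 2 in HAP1, 5 in HEK293FT, 1 in K562, 0 in MDA-MB-231 and 0 in THP1. For the lines with 0, the gNT guides with a negative change and an unadjusted p under 0.05 numbered 11 and 0, and DESeq2 called 0 and 0. The K562 and HEK293FT counts of gEss guides depended on single libraries: they were 7 without K562 day 14 replicate 2, 221 without day 14 replicate 1 and 51 with the replicate block, and 6 and 50 without HEK293FT day 14 and day 0 replicate 1.

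The main question of the screen was which gL guides were lost in each line. In HAP1, 4256 of 73165 gL guides were depleted at day 14 (5.82%, 95% exact interval 5.65% to 5.99%) and 1137 were enriched (1.55%). The depleted share exceeded that of gNT guides (0.2%), with an odds ratio of 30.8 and an adjusted p of 1.2e-21 in Fisher's exact test. The enriched share did not differ from that of gNT guides (1.6%, odds ratio 0.969, adjusted p = 1 in Fisher's exact test), so enriched gL guides in HAP1 were no more frequent than enriched controls. Guide gL_069166 fell from 142 and 119 reads at day 0 to 7 and 5 at day 14, and gL_070588 from 204 and 129 to 3 and 5 (log2 fold changes -4.73, SE 0.28, and -5.64, SE 0.36, edgeR adjusted p 2.48e-12 and 1.16e-11). Guides gL_068984 and gL_073035 rose, by log2 fold changes of 1.88 (SE 0.24) and 2.20 (SE 0.29), with edgeR adjusted p-values of 6.98e-07 and 8.38e-07. Depleted gL guides numbered 2257 at day 7 against day 0, and 698 from day 7 to day 14. Without day 14 replicate 2 the day 14 count was 6706, but 57 gNT guides were then called depleted too, and the day 7 to day 14 count was 337 without day 7 replicate 1, 2393 without day 14 replicate 2 and 0 in edgeR with HAP1 fitted alone (2296 at an unadjusted p under 0.05). The enriched count was 119 with HAP1 fitted alone, 641 with TMM factors from gNT guides, 365, 465 and 469 without day 0 replicates 1 and 2 and day 14 replicate 1, and 4312 without day 14 replicate 2.

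In MDA-MB-231, 4372 gL guides were depleted at day 14 (5.98%, 5.8% to 6.15%) and 108 were enriched (0.148%; 545 with the line fitted alone, 23 with TMM factors from gNT guides, and 22 and 50 without replicate 2 of day 0 and of day 14). The depleted share exceeded that of gNT guides, of which 0 were called, with an adjusted p of 2.53e-25 in Fisher's exact test. The enriched share was not above that of gNT guides (0.401%, odds ratio 0.367, adjusted p = 0.149 in Fisher's exact test). Guide gL_072205 fell from 204 and 311 reads at day 0 to 9 and 5 at day 14, and gL_063645 from 178 and 236 to 8 and 8 (log2 fold changes -5.66, SE 0.34, and -5.17, SE 0.32, edgeR adjusted p 4.09e-12 and 6.93e-12). The enriched guides gL_025636 and gL_059062 had log2 fold changes of 1.22 (SE 0.26) and 1.20 (SE 0.26), and edgeR adjusted p-values of 0.00102 and 0.00122, and gL_059062 did not pass without day 14 replicate 2. Depleted gL guides numbered 1870 at day 7 against day 0 and 759 from day 7 to day 14. Leaving out any of the line's libraries kept the day 14 count between 3112 and 4298, while the day 7 count fell to 1044 and 1115 without day 7 replicates 1 and 2. The day 7 to day 14 count fell to 207 without day 14 replicate 1 and to 410 and 362 without day 7 replicates 1 and 2.

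In THP1, 3027 gL guides were depleted at day 14 (4.14%, 3.99% to 4.28%) and 3 were enriched (390 with the line fitted alone and 7 without day 14 replicate 1). The depleted share exceeded that of gNT guides, of which 0 were called, with an adjusted p of 1.72e-17 in Fisher's exact test. Guide gL_064508 fell from 788 and 512 reads at day 0 to 18 and 29 at day 14, and gL_054302 from 589 and 312 to 13 and 18 (log2 fold changes -4.28, SE 0.26, and -4.30, SE 0.28, edgeR adjusted p 1.09e-11 and 2.53e-11). The enriched guides gL_060596 and gL_012621 had log2 fold changes of 2.06 (SE 0.33) and 1.48 (SE 0.26), with edgeR adjusted p-values of 4.29e-05 and 0.000167. Depleted gL guides numbered 1027 at day 7 against day 0 and 559 from day 7 to day 14. With THP1 fitted alone, and so with the smaller spread of its own libraries, the 3 counts were 4747, 2493 and 3080, and without any library of the line the day 14 count stayed between 2199 and 2925. The day 7 count fell to 662, 679, 461 and 262 without day 0 replicates 1 and 2 and day 7 replicates 1 and 2, and the day 7 to day 14 count to 185, 213, 147 and 63 without day 7 replicates 1 and 2 and day 14 replicates 1 and 2.

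In K562, 903 gL guides were depleted at day 14 (1.23%, 1.16% to 1.32%) and 54 were enriched (0.0738%; 1 with the line fitted alone, and 771 and 3 without day 14 replicates 1 and 2). The depleted share exceeded that of gNT guides (0.1%), with an odds ratio of 12.5 and an adjusted p of 0.000415 in Fisher's exact test. The enriched share was not above that of gNT guides (0.2%, odds ratio 0.368, adjusted p = 0.348 in Fisher's exact test). Guide gL_056126 fell from 191 reads at day 0 to 29 and 37 at day 14, and gL_027121 from 120 to 11 and 3 (log2 fold changes -2.57, SE 0.25, and -4.09, SE 0.46, edgeR adjusted p 1.85e-06 and 1.12e-05). The enriched guides gL_070773 and gL_039556 had log2 fold changes of 1.42 (SE 0.28) and 1.33 (SE 0.27), with edgeR adjusted p-values of 0.00426 and 0.00645, and neither passed when K562 was fitted alone or without day 14 replicate 2. At day 7 against day 0, 19 gL guides were depleted, a count that ran from 0 with K562 fitted alone (1682 at an unadjusted p under 0.05) and 1 with the replicate block or gNT-based TMM factors to 191 without spiked guides and 216 by DESeq2, with 94, 1, 45 and 46 without day 7 replicates 1 and 2 and day 14 replicates 1 and 2. From day 7 to day 14 edgeR called 0 gL guides, against 2491 that fell at an unadjusted p under 0.05 and 39 depleted by DESeq2, and edgeR called 37 without day 7 replicate 2 and 234 without day 14 replicate 1. The K562 day 14 count was 360 with the replicate block, and it rested on single libraries: it was 67 without day 14 replicate 2 and 2317 without day 14 replicate 1, where 27 gNT guides were also called.

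In HEK293FT, 827 gL guides were depleted at day 14 (95% exact interval 1.05% to 1.21% of those tested) and 128 were enriched (0.175%; 0 in edgeR with the line fitted alone, against 1482 at an unadjusted p under 0.05, 141 by DESeq2, 76 without spiked guides, 85 with the replicate block and 81 without day 0 replicate 1). The depleted share did not pass the test against gNT guides (0.501%), with an odds ratio of 2.27 and an adjusted p of 0.149 in Fisher's exact test. The enriched share was not above that of gNT guides (0.501%, odds ratio 0.348, adjusted p = 0.092 in Fisher's exact test). Of the depleted gL guides 254 (30.7%) were among the spiked guides, as were 3 of the 5 depleted gNT guides. With spiked guides dropped from these calls the counts were 573 gL and 2 gNT guides (odds ratio 3.93, p = 0.0284 in Fisher's exact test), and with a new edgeR fit without spiked guides 848 and 2 (odds ratio 5.83, p = 0.00142 in Fisher's exact test). Both tests lie outside the family of 40 tests and were chosen after the calls had been seen. Guide gL_048289 fell from 165 and 171 reads at day 0 to 15 and 19 at day 14 (log2 fold change -3.66, SE 0.48, edgeR adjusted p 0.000337). Guide gL_003745 had 1129 and 305 reads at day 0 and 164 and 84 at day 14 (log2 fold change -2.93, SE 0.35, edgeR adjusted p 0.000201; -1.72 without day 0 replicate 1). The enriched guides gL_064925 and gL_057128 each rested on 1 library, with 6521 against 151 reads and 173 against 6000 reads in the replicates of day 14, and neither passed without that library or with the line fitted alone (adjusted p 0.212 and 0.281 in edgeR). Depleted gL guides numbered 864 at day 7 against day 0 and 46 from day 7 to day 14. The latter count was 0 in edgeR with the replicate block (720 at an unadjusted p under 0.05) or with the line fitted alone (516 unadjusted), 1 or 2 without either day 14 library, 29 without day 7 replicate 1, 15 without spiked guides and 47 by DESeq2. The day 14 against day 0 count was 186 without day 14 replicate 1, 378 without day 0 replicate 1 and 285 with the line fitted alone, and the day 7 count 262 and 227 without day 7 replicates 1 and 2 and 381 without day 0 replicate 1.

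**Figure D2:**
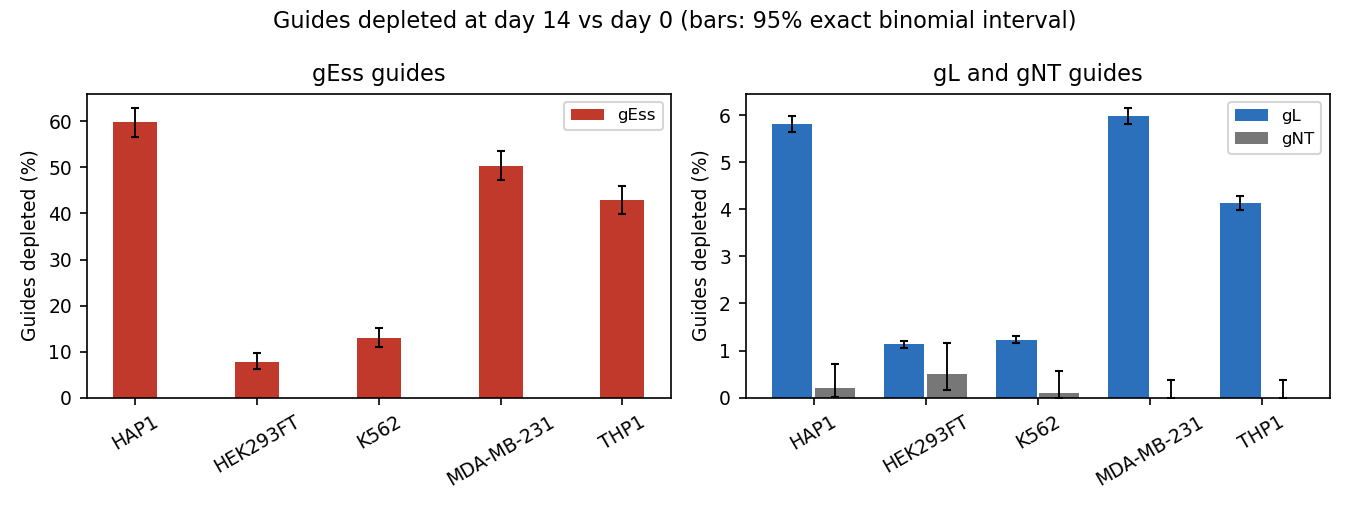
Percent of guides depleted at day 14 against day 0 in each line, for gEss guides (left) and for gL and gNT guides (right, another scale). Error bars are 95% exact binomial intervals over guides. The gL share is 5.98% in MDA-MB-231, 5.82% in HAP1, 4.14% in THP1 and 1.23% in K562, with an interval of 1.05% to 1.21% in HEK293FT, and the gNT share lies between 0% and 0.501%. For gL guides the intervals of K562 and HEK293FT overlap, and so do those of HAP1 and MDA-MB-231. The gL order within each of these pairs changed with the replicate block or thinning. For gEss guides the intervals of neither pair overlap, but with the replicate block K562 (51 gEss guides) fell below HEK293FT (76). With each line fitted alone, THP1 (4747 gL and 567 gEss guides) passed HAP1 (3186 and 517), so their order was not stable either.

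The 5 lines were compared to find gL guides lost in several of them. At day 14, 6653 gL guides were depleted in at least 1 line, 2308 in at least 3 lines and 231 in all 5. If the 5 lists were independent, 25.6 guides would be expected in at least 3 lines and 0.00147 in all 5. Of 998 gNT guides, 8 were depleted in 1 line and 0 in more than 1. Between pairs of lines, the day 14 log2 fold changes of gL guides correlated with a Pearson r of 0.293 (HEK293FT and K562) to 0.793 (MDA-MB-231 and THP1). The same r was 0.636 to 0.829 for gEss guides and -0.042 to 0.055 for gNT guides. These correlations are across guides, which are not independent replicates, and each line had its own day 0 libraries. Over gL guides, Spearman's rho was 0.088 to 0.256. The count in all 5 lines was bounded by the lines with fewest calls: it was 22 without HEK293FT day 14 replicate 1, 24 without K562 day 14 replicate 2, 135 without HEK293FT day 0 replicate 1 and 441 without spiked guides.

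**Figure D3:**
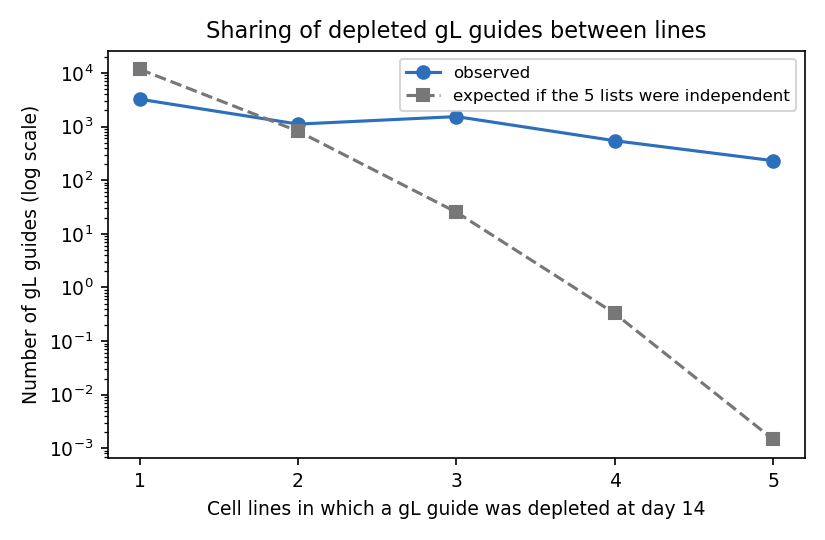
Number of gL guides depleted at day 14 in exactly 1 to 5 lines (circles) and the number expected if the 5 lists were independent (squares), on a log axis. Observed counts are 3235, 1110, 1533, 544 and 231 guides, against 11700, 819, 25.3, 0.327 and 0.00147 expected.

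Guides whose change differed between lines were tested directly, as the day 14 change of a line against the mean of the other 4. Of 998 gNT guides edgeR called 0 in either direction in HAP1, with 89 at an unadjusted p under 0.05. There, 1561 gL guides had a lower change than in the other lines (adjusted p = 7.07e-09 in Fisher's exact test). In MDA-MB-231 the number was 820 (adjusted p = 0.000105 in Fisher's exact test), in HEK293FT 507, in THP1 258 and in K562 32. The shares in HEK293FT, THP1 and K562 did not pass the test against gNT guides, with adjusted p-values of 1, 0.137 and 1 in Fisher's exact test. HEK293FT stood out on the other side, with 1665 gL guides of higher change against 4 gNT guides (odds ratio 5.79, adjusted p = 2.11e-05 in Fisher's exact test). HAP1 also passed on that side, with 463 gL guides against 0 gNT guides (adjusted p = 0.0104 in Fisher's exact test). A higher change can be a smaller loss or a larger gain, and these counts do not part them. Among gEss guides, 281 had a lower change in HAP1 than in the other lines and 247 a higher change in HEK293FT. The HAP1 count was 938 and 1038 without day 0 replicates 1 and 2 and 3871 without day 14 replicate 2, and the MDA-MB-231 count was 535 and 486 without day 0 replicates 1 and 2, 401 without day 14 replicate 1 and 1260 by DESeq2. The HEK293FT count was 298 without spiked guides, 219 without day 0 replicate 1 and 322 and 251 without day 14 replicates 1 and 2, the THP1 count 149 and 146, and the K562 count 424 and 21 (121 by DESeq2), each without day 14 replicates 1 and 2.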

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

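Of the tests in this part, those on the persistence of spikes, on the order of HEK293FT days and on depth were chosen after the results had been seen, while those on the class of spiked guides and on a common factor per line were fixed before their values were computed, apart from the gL slope as a second base and the count of guides less depleted in HAP1, which were added later, while the ratio with the gEss slope as the base alone had passed. Earlier versions of the persistence test were replaced, since they ruled out persistence by construction, pooled both days or took replicate numbers as pairs.

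The lines differed in their day 14 changes by a direct test in edgeR of each line against the mean of the other 4. The gL guides with a lower change than in the other lines numbered 1561 in HAP1, 507 in HEK293FT, 32 in K562, 820 in MDA-MB-231 and 258 in THP1. Those with a higher change numbered 463 in HAP1, 1665 in HEK293FT, 125 in K562, 35 in MDA-MB-231 and 50 in THP1. The gEss guides with a lower change numbered 281 in HAP1, 4 in HEK293FT, 55 in MDA-MB-231 and 26 in THP1. Those with a higher change numbered 9 in HAP1, 247 in HEK293FT, 29 in K562, 4 in MDA-MB-231 and 9 in THP1.

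The size of gEss depletion differed between lines. The gap between HAP1 and HEK293FT in the gEss median relative to gNT guides was -1.32 on the log2 scale at full depth. With all libraries thinned to 6209674 reads it was -1.34. This does not decide on depth as the cause. Thinning lowers all guides of a library by the same share on average, so it could hardly have moved this median, and the totals of these lines overlapped. A candidate explanation is 1 factor per line that scales the effect of every guide, such as knockdown strength or the number of divisions. The ratio of the gL slope to the gEss slope, each on the mean of the other 4 lines, was 0.799 in HAP1, 0.888 in HEK293FT, 1.00 in K562, 0.979 in MDA-MB-231 and 0.958 in THP1, where a common factor was expected to keep the slopes within 25%, and in HAP1 they lay 20.1% apart with the gEss slope as the base and 25.2% with the gL slope, so this value did not decide. HAP1 slopes lay above 1 (bootstrap intervals 1.80 to 1.98 for gEss and 1.48 to 1.53 for gL). Yet 47 of 2575 gL guides depleted in 2 or more other lines were less depleted in HAP1 (1.83%, 95% exact interval 1.34% to 2.42%). Among gEss guides it was 3 of 407 (0.152% to 2.14%), and 0 of 992 gNT guides had a higher change (upper end 0.371%). These counts do not decide either. The gL and gEss guides were chosen by low values in the same lines that the test subtracts, and the gNT guides were not. A common factor, and line-specific needs for the targets, stay open.

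In HEK293FT, depletion in the libraries labelled replicate 2 was smaller at day 14 than at day 7. The median change per guide was 0.25 on the log2 scale in gEss guides. In the 2300 gL guides depleted in at least 3 of the other 4 lines it was 0.51 (95% bootstrap interval 0.49 to 0.53). Without spiked guides the gEss value was 0.25 (0.23 to 0.29) in 995 of 1000 guides. That value could hardly have moved, since a scale distorted by spikes cancels against the gNT guides of the same library. It is thus no test of spikes as the cause. An exchange of the day 7 and day 14 labels within replicate 2 is consistent with the gL value of 0.51, which could have come out at or below 0, but weaker knockdown, or outgrowth of cells without it, in replicate 2 after day 7 predicts the same, with replicate 1 moving on (-0.48 in the same gL guides). Over all guides, day 7 replicate 1 correlated more with day 14 replicate 2 (0.759) than with day 7 replicate 2 (0.739), and day 14 replicate 1 more with day 7 replicate 2 (0.735) than with day 14 replicate 2 (0.695), as both explanations predict. Over gNT guides, with the THP1 profile removed, the same pairs went both ways (0.44 against 0.416, and 0.257 against 0.272), so these values do not part the explanations. The labels were kept, and the day 14 count of depleted gL guides was 681 without both later libraries of replicate 2.

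In HEK293FT, 380 guides showed lone-library spikes: 151 in day 0 replicate 1, 113 in day 0 replicate 2, and 16 to 53 in each later library. Growth of a cell clone carrying the guide is argued against for spikes at day 0: of 280 guides over 10 times above both the other library of the day and the mean of the other lines, 4 (1.43%, 95% exact interval 0.391% to 3.62%) were still at least 2 times above the mean of the other lines in either library of day 7, as were 1.33% of the other guides. This takes replicate numbers not as pairs, but needs the day 7 cells to descend from the infections sampled at day 0. From day 7 to day 14 it was 6 of 50 (12%, 4.53% to 24.3%), against 3.88% of the other guides, so clones stay open for spikes at day 7, and spikes at day 14 have no later library. An event in the amplification or sequencing of single libraries, unrelated to the guide, would strike gNT and gL guides alike. Spikes were seen in 0.6% of gNT guides (6 of 1000, 95% exact interval 0.22% to 1.3%) and in 0.504% of gL guides. Growth of a clone for reasons other than its guide would also strike the classes alike, so these shares do not part the explanations.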

How the results depend on the processing

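Thinning, the removal of spiked guides and the removal of 1 replicate's later libraries in HEK293FT or K562 were chosen after seeing the data. No day 14 gEss median relative to gNT guides and no named guide's log2 fold change reversed under any alternative run. The median change per gEss guide from day 7 to day 14, set by replicate alone, was -0.18 in HEK293FT replicate 1 and 0.25 in replicate 2. Of the counts and values that answer the comparisons, 313 stayed within 1.5 times the main value and 97 did not. Of the others (counts held to the same 1.5 times, gEss medians to 1 SD between replicates and named guides to their call), 442 stayed, 71 moved and 10 enriched-guide calls were lost, in HEK293FT, K562 and MDA-MB-231. The cause of a move was not tested unless stated. The planned target-level alternatives (summed counts per target, another RRA alpha, ranks among gNT guides, targets without their strongest guide, adjustment over a list alone) were not run, since guides were not mapped to targets. Fitting each line alone gives no value against the other lines, and leaving out the lone K562 day 0 library gives none against day 0 or over all 5 lines.

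DESeq2 size factors and no filter moved no such count. DESeq2's own test called 216 gL guides depleted in K562 at day 7 against day 0, 39 from day 7 to day 14 and 121 against the other lines, 1212 (day 7 to day 14) and 1260 (against the other lines) in MDA-MB-231, 1037 in THP1 from day 7 to day 14, and 348 in all 5 lines. TMM factors from gNT guides gave 1 for K562 at day 7. A mean count of at least 100, which removes guides made rare by depletion, gave 34 gEss guides in HEK293FT and 60 in K562 at day 14, 440 gL guides in K562 at day 14, 1185 at day 7 in MDA-MB-231, 497 at day 7 in THP1 and 76 in all 5 lines. Each line fitted alone, with its own spread and fewer residual degrees of freedom, gave 285 gL and 42 gEss guides in HEK293FT and 451 and 86 in K562 at day 14, 4747 gL guides in THP1 at day 14, 2493 at day 7 and 3080 from day 7 to day 14. It gave 297 in HEK293FT at day 7, 0 in K562 at day 7 (1682 at an unadjusted p under 0.05), and from day 7 to day 14 0 in HAP1 (2296 unadjusted) and 0 in HEK293FT (516 unadjusted). Thinning gave 460 in MDA-MB-231 and 283 in THP1 from day 7 to day 14, a limit set by depth, and moved no day 14 against day 0 count of depleted gL or gEss guides beyond 1.5 times.

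Enriched gL guides at day 14, 1137 in HAP1, 128 in HEK293FT, 54 in K562, 108 in MDA-MB-231 and 3 in THP1, were 119, 0, 1, 545 and 390 in that order with each line fitted alone. They were 641 in HAP1 and 23 in MDA-MB-231 with TMM factors from gNT guides, and 159 in K562 and 264 in MDA-MB-231 by DESeq2. Without single libraries they reached 4312 in HAP1 (day 14 replicate 2; 365, 465 and 469 without day 0 replicates 1 and 2 and day 14 replicate 1), 771 and 3 in K562 (day 14 replicates 1 and 2), 81 in HEK293FT (day 0 replicate 1), 22 and 50 in MDA-MB-231 (day 0 and day 14 replicate 2) and 7 in THP1 (day 14 replicate 1). With a mean count of at least 100 the gEss median relative to gNT guides was -1.20, -0.21, -0.26, -0.82 and -0.48 in the same order, against -1.61, -0.29, -0.36, -1.11 and -0.73 in the edgeR test of all 75163 guides, so the lines kept their ranks.

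Without spiked guides the gL counts were 332 in HAP1, 15 in HEK293FT and 947 in THP1 from day 7 to day 14, 191 in K562 at day 7, 298 in HEK293FT against the other lines and 441 in all 5 lines. Without HEK293FT replicate 2 of days 7 and 14 they were 200 at day 7 and 203 against the other lines. Without K562 replicate 1 of days 7 and 14 they were 2581 at day 14, 211 at day 7, 96 from day 7 to day 14 and 585 against the other lines, with 228 gEss guides, but 30 of 998 gNT guides were then depleted at day 14 against 1 in the main test.

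Replicate numbers were shared between days, but the labels do not tie a number to an infection. Deviations of same-numbered libraries correlated by 0.038 to 0.129 between day 0 and later days and by 0.148 to 0.418 between days 7 and 14, where all 5 lines were over 0.1. With 2 libraries per group a line had under 3 pairs, so the main test did not pair by number. The medians set by replicate did, and the values for days 7 and 14 hint at such pairs. With the replicate block, K562 had 360 gL and 51 gEss guides depleted at day 14 and 1 gL guide at day 7, HEK293FT had 0 from day 7 to day 14 (720 unadjusted), and 117 were depleted in all 5 lines. The block also gave 85 enriched gL guides in HEK293FT, 32 in K562 and 226 in MDA-MB-231 at day 14, and 8 depleted gNT guides in HAP1 against 2, and the other counts stayed within 1.5 times.

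Leaving out each library of a line in turn, with a lone library assumed to vary like the other groups, gave these ranges of depleted gL guides. Day 14 against day 0: 3587 to 6706 in HAP1 (highest without day 14 replicate 2), 186 to 843 in HEK293FT (186 without day 14 replicate 1, 378 without day 0 replicate 1), 67 to 2317 in K562 (without day 14 replicates 2 and 1), 3112 to 4298 in MDA-MB-231 and 2199 to 2925 in THP1. For gEss guides, in the same order of lines as in all ranges that follow: 548 to 601, 6 to 111 (6 and 50 without those HEK293FT libraries), 7 to 221 (without the same K562 libraries), 406 to 504 and 335 to 418. Day 7 against day 0: 1727 to 2482, 227 to 919 (227 and 262 without day 7 replicates 2 and 1, 381 without day 0 replicate 1), 1 to 94 (without day 7 replicates 2 and 1; 45 and 46 without day 14 replicates 1 and 2), 1044 to 1918 (1044 and 1115 without day 7 replicates 1 and 2) and 262 to 1000 (262 and 461 without day 7 replicates 2 and 1, 662 and 679 without day 0 replicates 1 and 2). Day 7 to day 14: 337 to 2393 (without day 7 replicate 1 and day 14 replicate 2), 1 to 53 (1 and 2 without day 14 replicates 2 and 1, 29 without day 7 replicate 1), 0 to 234 (234 without day 14 replicate 1, 37 without day 7 replicate 2; 0 without day 0 replicate 1, day 7 replicate 1 or day 14 replicate 2, with 2313 to 3310 unadjusted), 207 to 658 (207 without day 14 replicate 1, 410 and 362 without day 7 replicates 1 and 2) and 63 to 450 (63 and 147 without day 14 replicates 2 and 1, 185 and 213 without day 7 replicates 1 and 2). Against the other lines: 938 to 3871 (938 and 1038 without day 0 replicates 1 and 2, 3871 without day 14 replicate 2), 219 to 555 (219 without day 0 replicate 1, 322 and 251 without day 14 replicates 1 and 2), 21 to 424 (without day 14 replicates 2 and 1), 401 to 794 (401 without day 14 replicate 1, 535 and 486 without day 0 replicates 1 and 2) and 146 to 242 (149 and 146 without day 14 replicates 1 and 2). In all 5 lines: 22 to 314 (22, 24 and 135 without HEK293FT day 14 replicate 1, K562 day 14 replicate 2 and HEK293FT day 0 replicate 1).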

Other observations

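The tests in this part were chosen after the results had been seen.

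Guides with neighbouring gL numbers changed together. Over consecutive numbers, the day 14 log2 fold changes of gL guides correlated with an r of 0.289 in HAP1, 0.079 in HEK293FT, 0.149 in K562, 0.306 in MDA-MB-231 and 0.32 in THP1. The highest of 1000 shuffled orders was 0.012 or 0.013 in each line. The correlation fell at each step up to a distance of 6 numbers, where it was 0.017, -0.001, 0.012, 0.039 and 0.024 in the same order of lines. At a distance of 10 numbers it was 0.002, -0.006, 0.002, 0.029 and 0.007 in the same order of lines, at 20 it was 0.019, -0.001, 0.009, 0.038 and 0.017, and at 50 it was 0.016, 0.002, -0.003, 0.03 and 0.015. For gNT guides no neighbour correlation exceeded its shuffled orders. A slow trend along the numbering is argued against as the cause, since the correlation at a distance of 10 was at most 0.0943 of that between neighbours, although values above the shuffled orders at 20 and 50 in HAP1, MDA-MB-231 and THP1, and at 10 in MDA-MB-231, were not explained. A candidate explanation is that consecutive numbers share a target, which was not decided here, since the lowest neighbour correlation, 0.079 in HEK293FT, restates the pattern that led to the idea. Earlier rules for this idea also used the distances of 20 and then 50, and the first had come out in its favour. Over gEss guides the correlation of neighbours was 0.289 (K562) to 0.471 (THP1), and at a distance of 10 it was 0.004 (K562) to 0.117 (THP1).

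Depleted gL guides formed runs of consecutive numbers. In HAP1, 171 runs of 4 or more consecutive depleted guides were seen at day 14, against at most 3 in 100 shuffled orders, and in MDA-MB-231 there were 151 against at most 5. THP1 had 89 runs against at most 3, with the longest of 11 guides, and K562 had 8 against 0. HEK293FT had no such run at an adjusted p under 0.05 in edgeR, among 827 depleted gL guides. Guides depleted in at least 3 lines formed 54 runs, against at most 2 in the shuffled orders. Runs of guides with a lower change in a line than in the other lines numbered 21 in HAP1, 14 in MDA-MB-231 and 7 in THP1, against at most 1, 0 and 0.

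A few runs are given as examples chosen after their values were seen. The 6 guides from gL_054302 to gL_054307 were all depleted in THP1 at day 14, with log2 fold changes of -5.26 to -1.28, and edgeR called none of them in the other 4 lines, where their medians were 0.19 in HAP1, -0.20 in HEK293FT, 0.23 in K562 and -0.14 in MDA-MB-231. The 4 guides from gL_058784 to gL_058787 went in opposite directions between lines. All 4 were enriched in HAP1 (median log2 fold change 2.96) and 3 in MDA-MB-231 (median 1.75), while 3 were depleted in THP1 (median -2.53) and 2 in K562 (median -1.83). The 6 guides from gL_060592 to gL_060597 were all depleted in HAP1 (median -3.38) and 5 of them in MDA-MB-231 (median -2.68). In THP1, 3 of these 6 were depleted and 1, gL_060596, was enriched with a log2 fold change of 2.06, so that guide departed from its neighbours in the line where it had the smallest p among enriched gL guides.

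Depletion was unevenly spread along the numbering. Among gL guides numbered 50001 to 60000, 12.5% were depleted at day 14 in MDA-MB-231, 10.7% in HAP1, 7.38% in THP1 and 2.13% in K562. Among those numbered 20001 to 30000 the shares were 3.07%, 3.59%, 2.48% and 0.892%. In HEK293FT the shares were 1.23% and 0.871%.

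Over gNT guides, with the THP1 profile removed, HEK293FT day 7 replicate 1 correlated with HAP1 day 0 replicates 1 and 2 by 0.468 and 0.414, while these 2 HAP1 libraries correlated with each other by 0.338. Its correlation was 0.247 and 0.311 with HEK293FT day 0 replicates 1 and 2, 0.416 with HEK293FT day 7 replicate 2 and 0.44 with HEK293FT day 14 replicate 2. Over all guides its closest library was HEK293FT day 14 replicate 1 (0.791).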
